A study of Staphylococcus aureus with 6 samples.

How the data were processed

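RNA was sequenced from 2 strains of the bacterium Staphylococcus aureus, Newman and N315, each with 3 libraries from cultures in exponential growth. Per the labels' protocols, cells were broken mechanically with beads, RNA was taken up in phenol and chloroform, ribosomal RNA was removed with a bacterial Ribo-Zero kit, and libraries were made with a directional NEBNext kit, which keeps the strand of each RNA. The authors deposited 1 file of raw read counts per library, with 1 whole number per feature and no normalization. FastQC, BWA and HTSeq are the tools named in the submitters' processing notes. Their versions, the genome builds, the annotation, the mapping quality threshold and the strand setting are not given in the sources used here. HTSeq gives a read to a feature only when the read overlaps 1 feature, so reads over overlapping features and reads from repeated sequences are set aside. This lowers the counts of RNAs that overlap a gene and of RNAs present in several copies.

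The Newman files list 3132 features, of which 2624 are genes under NWMN_ locus tags and 505 are small RNAs under srn_ identifiers. The N315 files list 3112 features, of which 2593 are genes under protein accessions and 516 are small RNAs. Both also list the RNAs named 4.5S, RNAseP and tmRNA. The files do not pair srn_ identifiers, locus tags or accessions with gene names, and 0 of these identifiers occurred in the reference gene table used for names, which describes another strain (assembly ASM1342v1). No gene of Newman could therefore be matched to its N315 counterpart, and only the 483 features with the same identifier in both strains, 480 srn_ identifiers and the 3 named RNAs, were compared between strains. The files give no coordinates or lengths, so positions are not reported, and a small RNA may have been counted over different lengths in the 2 annotations.

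Counter lines that name no gene were kept out of library sizes and tests. Ambiguous reads made up 34.9% ± 4.26 (SD, n = 3) of all reads in the Newman files and 4.84% ± 0.607 (SD, n = 3) in the N315 files. Reads of low mapping quality made up 1.60% ± 1.29 (SD, n = 3) in Newman and 72.7% ± 4.55 (SD, n = 3) in N315. Reads outside any feature made up 4.58% ± 0.517 (SD, n = 3) and 1.95% ± 0.0749 (SD, n = 3).

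Samples were grouped by the strain in their titles. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Each pair of replicates differed by more than sampling noise: the chi-square statistic per degree of freedom ranged from 17.1 to 674, and each library was counted as 1 replicate. The comparison used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with trimmed mean of M values (TMM) scaling, edgeR's default low-count filter and Benjamini-Hochberg adjustment, and RNAs with an adjusted p under 0.05 were called. The filter kept 189 of the 483 shared features. Library size was the sum over these 189 RNAs. Normalised CPM values are therefore relative to the reads of the tested RNAs, rescaled by TMM factors from 0.572 to 1.97, and can exceed the RNA's share of those reads. Log2 fold changes are Newman minus N315, with a standard error (SE) derived from the F statistic. For RNAs at 0 in all 3 libraries of a strain, the fold is a lower bound against 3 counts over that strain's 3 libraries, at TMM-scaled library sizes. An RNA or gene was taken as expressed in a strain when it had at least 10 counts in all 3 libraries. Exact intervals of read shares and floors cover counting error only, because reads without molecular identifiers are not independent molecules, whereas intervals of log2 fold changes come from the SE and include the spread between libraries.

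Before the data were examined, the design, the alternatives, 18 gene lists and the rule for named RNAs were fixed. Under that rule the RNAs with the largest folds were taken, 10 in each direction, among those called, with non-overlapping libraries and a mean of at least 10 CPM. Up to 4 measured members of each list were also taken, with RNAIII if measured, and within each strain the 10 features with the highest share of reads and the 5 most abundant ones listed for that strain alone. No feature carries the name RNAIII in the files, and which srn_ identifier stands for it is not given in the sources used here, so it may be among the RNAs tested under its identifier. Because identifiers without names carry little meaning, only 2 identifiers in each direction are given, the one with the largest fold and the one with the largest fold among those with more than 3 counts in the other strain. This restriction, and the naming of srn_4470, were chosen after the values were seen. The lists covered the agr system, housekeeping RNAs, Rsa, Spr and SigB-dependent small RNAs, the SaeRS and SigB regulons, SCCmec, capsule, ribosomal proteins, heat shock, glycolysis, fermentation and nitrate respiration, iron uptake, surface and secreted proteins, riboswitches, tRNA and rRNA. Only the list of housekeeping RNAs had members with matching names, 3 of them, and the text pattern for rRNA also caught 4.5S, which is not a ribosomal RNA. No list reached the 5 members needed for a set test, so no set test was run.

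The test was checked on simulated data made for the Newman and N315 comparison from the means, library sizes and dispersions of the 483 shared RNAs. Over 20 runs with 48 changed RNAs each and a mean of 187.1 RNAs tested, it called 29.6% of 2-fold changes, 83.2% of 4-fold changes and 99.7% of 8-fold changes with the right sign, and 5.29% of its calls were false. Apart from the changed RNAs, as many raised as lowered, both simulated strains had the same mean shares. These rates therefore do not cover errors from scaling between strains of unlike composition. Alternatives were RLE and total-count scaling, other library sizes, DESeq2 1.42.0, limma-voom (limma 3.58.1), other count filters, removal of RNAs above 5% of assigned counts, the replicate number as a block, and leaving out each library in turn. Single values per library were compared by exact permutation tests, two-sided, for which 3 against 3 libraries cannot go below p = 0.1.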

Results

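The series asked which regulatory RNAs catalogued for staphylococci were transcribed in 2 strains of Staphylococcus aureus. Newman is a methicillin-susceptible laboratory strain and N315 is a methicillin-resistant clinical strain. Ribosome-depleted RNA from exponential growth was sequenced in 3 libraries per strain. Reads assigned to features numbered 5510975, 7572778 and 7781040 in Newman replicates 1, 2 and 3, and 1100745, 998218 and 1795828 in N315 replicates 1, 2 and 3. The 483 RNAs listed for both strains took 1449513 to 1562262 reads per Newman library and 441429 to 660740 reads per N315 library. A count of 3 corresponded to 0.386 to 0.544 CPM of assigned reads in Newman and to 1.67 to 3.01 in N315, so weakly transcribed RNAs were measured less precisely in N315.

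**Figure D1:**
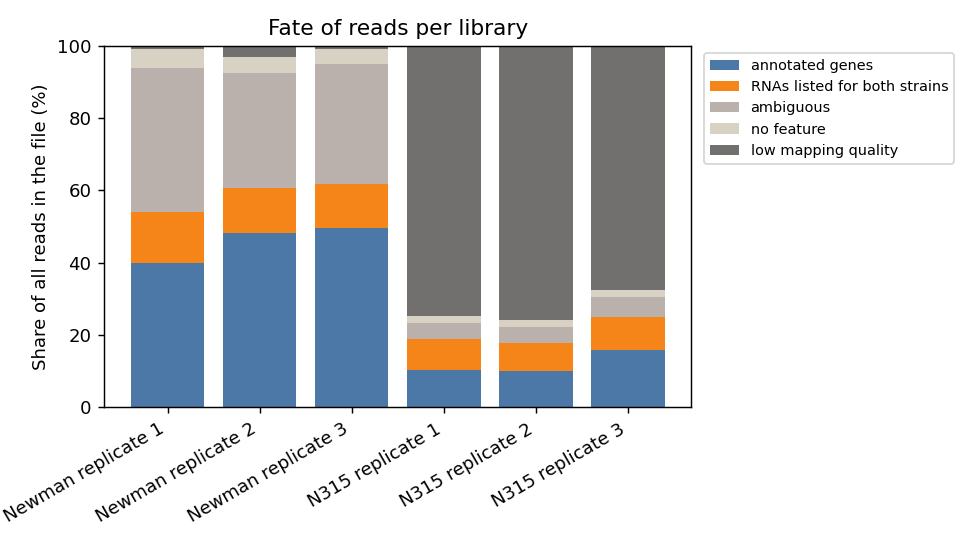
Share of all reads in each library's file (%, vertical axis) that were assigned to annotated genes or to RNAs listed for both strains, or were set aside as ambiguous, outside features or of low mapping quality. Reads of low mapping quality made up 67.4% to 75.9% of the N315 libraries and 0.777% to 3.09% of the Newman libraries; reads of small RNAs listed for 1 strain alone are too few to be drawn.

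The counted levels of many small RNAs listed for both strains differed widely between the strains in exponential growth. The files of the strains also differed in the share of reads set aside, and the annotated lengths may differ. The differences therefore cannot be credited to transcription alone. Of 189 RNAs tested, 44 were higher in Newman and 55 were higher in N315 (edgeR quasi-likelihood test, adjusted p under 0.05), and 90 did not pass the test. The called RNAs included 98 of the 186 srn_ small RNAs, 44 higher in Newman and 54 higher in N315, and the count was again 98 when adjusted over the list alone. With RNAs at 0 in a strain taken at their lower bound, 45 called RNAs differed by over 8-fold, 23 of them higher in Newman and 22 higher in N315. Of these, 18 differed by over 64-fold, 9 in each direction. A further 48 differed by 2-fold to 8-fold, 17 higher in Newman and 31 higher in N315. By normalised CPM, the libraries of the strains did not overlap for 116 RNAs (61.4%), where chance gives 10%, and 96 of these were called. A shift in scaling between the strains also separates libraries, so this count depends on the TMM scaling. It included tmRNA and RNAseP, whose signs turned with total-count scaling.

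Among the RNAs higher in Newman with more than 3 counts over the N315 libraries, srn_3910 had the largest fold. It reached 61314 ± 21279 normalised CPM (SD, n = 3) in Newman and 257 ± 333 (SD, n = 3) in N315, a log2 fold change of 7.92 (SE 1.06, adjusted p = 0.00022 by edgeR). It took 1.96% ± 0.148 (SD, n = 3) of all assigned reads in Newman and 0.00682% ± 0.00858 (SD, n = 3) in N315. Its N315 level rested on replicate 1, with 641 CPM against 77.2 and 52.3 in replicates 2 and 3, and without that library the log2 fold change was 10.03 (adjusted p = 9.6e-07 by edgeR). With the same limit on the Newman libraries, srn_1590 had the largest fold among the RNAs higher in N315, at 39230 ± 20301 CPM (SD, n = 3) in N315 and 135 ± 16.2 (SD, n = 3) in Newman, a log2 fold change of -8.18 (SE 0.56, adjusted p = 2.4e-06 by edgeR). Over the alternatives run, the log2 fold change ranged from 7.49 to 10.03 for srn_3910 and from -8.41 to -6.97 for srn_1590. By mean share, srn_1590 was the most abundant srn_ RNA of N315 after srn_4470, at 1.07% ± 0.517 (SD, n = 3) of assigned reads.

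Some RNAs were read in 1 strain alone, although reads set aside before counting, which outnumber those these RNAs lack, were not counted. Of the called RNAs, 7 had 0 counts in all 3 N315 libraries and 5 had 0 counts in all 3 Newman libraries. The largest fold of the first kind belonged to srn_2230, at 10871 ± 2569 CPM (SD, n = 3) in Newman and at least 3795-fold higher there, from counts pooled over libraries, than the limit that 3 counts over the N315 libraries set; the bound was 2052-fold without N315 replicate 3. The largest of the second kind belonged to srn_4710, at 6054 ± 3515 CPM (SD, n = 3) in N315 and, with TMM scaling, at least 15602-fold higher there by the same pooled measure. That bound rested on N315 replicate 3 and was 9761-fold without it, and it was 9199-fold without Newman replicate 1. All these bounds depend on the TMM factors, 1.29 to 1.97 in Newman and 0.572 to 0.753 in N315. Without these factors the bounds of RNAs at 0 in Newman would be lower and those of RNAs at 0 in N315 higher. Bounds under other scalings were not computed. For the 7 RNAs at 0 in N315 the bounds ran from 3.42-fold to 3795-fold with a median of 31.1-fold, and for the 5 RNAs at 0 in Newman from 663-fold to 15602-fold with a median of 1396-fold. Among all 99 called RNAs, 14 of those higher in Newman and 6 of those higher in N315 had 3 or fewer counts in the other strain, so their folds are poorly fixed.

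**Figure D2:**
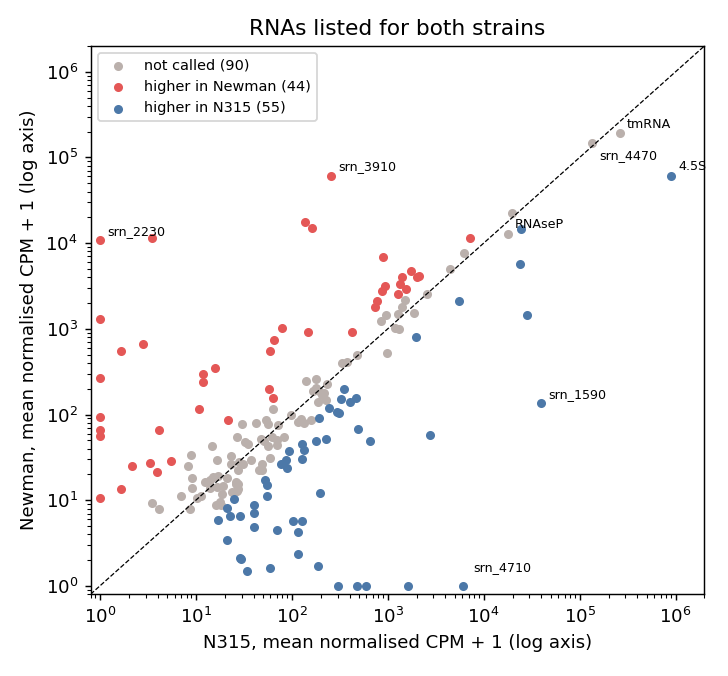
Mean normalised CPM plus 1 of 189 tested RNAs in N315 (horizontal log axis) and Newman (vertical log axis), coloured by the edgeR call; the dashed line marks equal levels. The 44 RNAs higher in Newman and 55 higher in N315 spread far from the line, with srn_3910 and srn_2230 on the Newman side, srn_1590, srn_4710 and 4.5S on the N315 side, and tmRNA and RNAseP near it.

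The split of calls between the strains depended on how libraries were scaled and on the low-count filter. The median log2 fold change of the tested RNAs was -0.19 with TMM and 0.99 when libraries were scaled to their total counts. With total counts 81 RNAs were higher in Newman and 26 were higher in N315. More RNAs were also higher in Newman with RLE (53 against 45), DESeq2 (52 against 45) and all assigned reads without TMM (44 against 39). The same held with no low-count filter (76 against 67). All other alternatives, which include leaving out each library, gave more RNAs higher in N315. Replicate 1 of Newman stood apart from the others, and without it 105 RNAs were called, 38 higher in Newman and 67 higher in N315, which included 83 of the 91 original calls that were still tested.

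The list of housekeeping RNAs had 3 measured members, of which 1 was higher in N315 and 2 did not pass the test. The 4.5S RNA, the RNA part of the signal recognition particle that targets proteins for export, was 14.5-fold higher in N315, with a log2 fold change of -3.86 (SE 0.30, adjusted p = 6.5e-06 by edgeR). The change was smaller with total-count scaling, at -2.64, and with no low-count filter, at -3.0. It took 24.7% ± 3.73 (SD, n = 3) of assigned reads in N315 and 2.13% ± 0.81 (SD, n = 3) in Newman. The tmRNA, which frees stalled ribosomes, had a log2 fold change of -0.44 (95% interval -1.0 to 0.11, adjusted p = 0.16 by edgeR). The RNA of RNase P, the enzyme that trims the 5′ ends of tRNAs, had one of -0.47 (95% interval -0.99 to 0.05, adjusted p = 0.12 by edgeR). Both signs turned with total-count scaling, at 0.76 for tmRNA (adjusted p = 0.034 by edgeR) and 0.74 for RNAseP (adjusted p = 0.070 by edgeR), and with no low-count filter, at 0.39 and 0.38 (adjusted p = 0.48 by edgeR for each).

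Ratios within a library do not depend on scaling. There were 14.9 ± 0.883 (SD, n = 3) tmRNA reads per RNAseP read in Newman and 14.8 ± 0.650 (SD, n = 3) in N315, a difference smaller than the spread between replicates (exact permutation p = 0.7, two-sided). There were 0.325 ± 0.0683 (SD, n = 3) 4.5S reads per tmRNA read in Newman and 3.40 ± 0.272 (SD, n = 3) in N315, which is 10.5 times as many and without overlap between libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow).

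**Figure D3:**
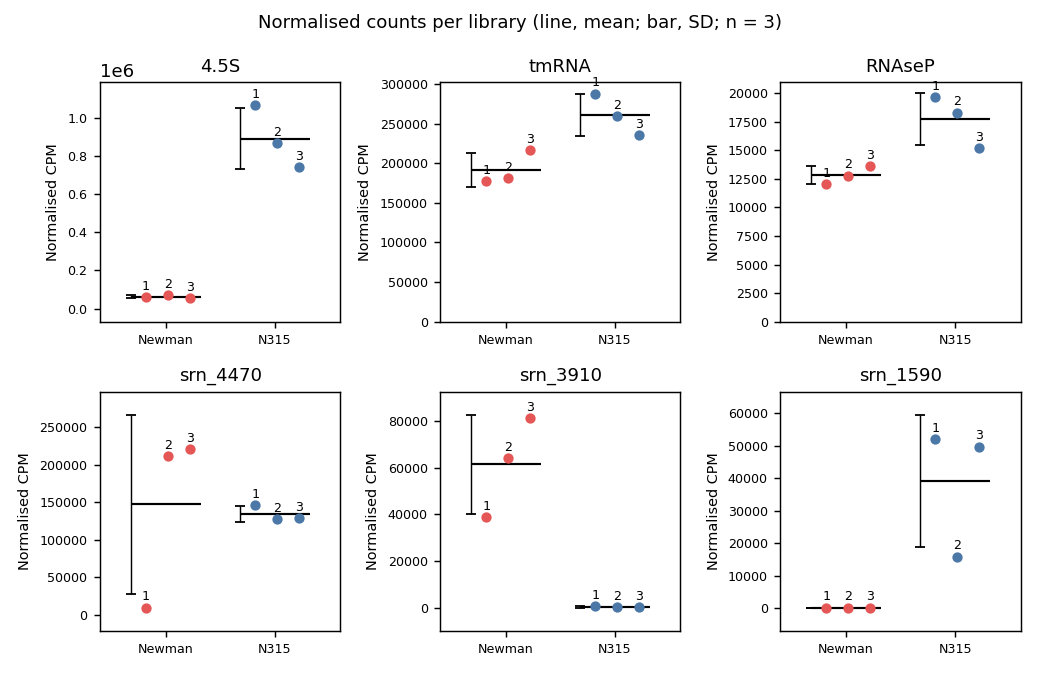
Normalised CPM (vertical axes, from a linear zero) of 6 RNAs in the 3 Newman and 3 N315 libraries; digits give the replicate, lines the mean and bars the SD. The 4.5S RNA lies at 55195 to 70978 in Newman and 742925 to 1064088 in N315, and srn_4470 lies at 9433 in Newman replicate 1 against 211843 and 220344 in replicates 2 and 3.

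The RNAs listed for both strains took 42.2% ± 4.76 (SD, n = 3) of assigned reads in N315 and 22.3% ± 3.52 (SD, n = 3) in Newman (exact permutation p = 0.1, two-sided, the smallest possible). Of all reads, those set aside included, the same RNAs took more in Newman, 13.0% ± 1.07 (SD, n = 3), than in N315, 8.56% ± 0.666 (SD, n = 3). The direction therefore depended on whether the reads set aside were included. The difference in the share of assigned reads lay mostly in 4.5S. The RNAs left out below were also taken out of the assigned reads, so these shares are of the remaining assigned reads. Without 4.5S alone the share was 20.6% in Newman and 23.3% in N315. Without tmRNA and srn_4470, the other RNAs above 5% of assigned reads in some library, it was 13.0% and 35.1%, and without all 3 it was 10.9% and 10.2%.

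Expressed small RNAs were a minority of those listed. In Newman 178 of 505 srn_ RNAs (35.2%) and 2243 of 2624 genes (85.5%) were expressed, with at least 10 counts in all 3 libraries. In N315 109 of 516 srn_ RNAs (21.1%) and 2066 of 2593 genes (79.7%) were expressed. With each library thinned to 998218 assigned reads, 103 srn_ RNAs were expressed in Newman and 105 in N315, and the order of the genes turned, with 1755 expressed in Newman and 2030 in N315. With the reads of srn_ RNAs alone thinned to 101104 per library, 94 srn_ RNAs were expressed in Newman and 106 in N315. Of the 480 srn_ RNAs listed for both strains, 92 were expressed in both, 79 in Newman and not N315, 13 in N315 and not Newman, and 296 in neither at these depths. Independent lists would share 37.4 (Fisher's exact test across RNAs, which are not independent replicates, two-sided p = 2.4e-36). Reads were concentrated in few features, with the 10 most abundant taking 26.2% ± 2.03 (SD, n = 3) of assigned reads in Newman and 43.6% ± 4.18 (SD, n = 3) in N315. In Newman tmRNA had the highest mean share, 6.60% ± 2.25 (SD, n = 3). This rank rested on replicate 1, since srn_4470 exceeded tmRNA in replicates 2 and 3, at 5.92% and 5.63% against 5.07% and 5.53%. The gene with the highest mean share in Newman, locus tag NWMN_0783, took 2.83% ± 0.402 (SD, n = 3). In N315 tmRNA came after 4.5S, with 7.25% ± 0.659 (SD, n = 3), and the gene with the highest mean share, protein accession BAB41326, took 1.67% ± 0.748 (SD, n = 3). In both strains the gene with the most reads differed between libraries.

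The replicates of Newman were unevenly alike. Over 2406 features, log2 CPM of replicates 2 and 3 correlated across features with r = 0.995, whereas replicate 1 correlated with them at 0.902 and 0.905. No feature differed by over 4-fold between replicates 2 and 3, but 181 differed between replicates 1 and 2 and 180 between replicates 1 and 3. In N315 over 2104 features the correlations were 0.979 for replicates 1 and 3, 0.947 for 1 and 2 and 0.942 for 2 and 3. The abundant srn_4470 showed the contrast: it took 0.489% (exact 95% interval 0.483% to 0.495%) of assigned reads in Newman replicate 1, and 5.92% (5.90% to 5.94%) and 5.63% (5.61% to 5.64%) in replicates 2 and 3. In N315 it took 3.73% ± 0.138 (SD, n = 3), and the difference between strains did not pass the test (log2 fold change 0.13, 95% interval -1.70 to 1.97, adjusted p = 0.91 by edgeR).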

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

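The tests of depth on the RNAs at 0 were chosen after the counts had been seen, and the test of the reads set aside before its value was known.

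From data outside the comparison, 4 mean values were set down without a test. Reads of low mapping quality made up 72.7% of all reads in the N315 files on average, and ambiguous reads made up 34.9% of those in the Newman files. Of the 25 srn_ identifiers listed for Newman alone, 7 were expressed, led by srn_9360 at 421 ± 197 CPM of assigned reads (SD, n = 3). Of the 36 listed for N315 alone, 4 were expressed, led by srn_0160 at 39.1 ± 6.90 CPM (SD, n = 3).

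The reads set aside bear on the 12 called RNAs with 0 counts in all libraries of a strain. Lower depth is argued against for the 5 RNAs at 0 in Newman, because the Newman library with the fewest assigned reads held 3.07 times those of the largest N315 library. For each of the 7 RNAs at 0 in N315, the N315 libraries would hold at least 10.3 reads in total at the level of Newman. An RNA had to be expected at such a count to be called, so this minimum was fixed by the selection and decides nothing. The median expected total was 93.3 reads and the highest 11386, against 0 reads counted. These values argue against lower depth for the RNAs at or above the median, and lower depth stays open for those nearer the minimum. Loss of reads of the 12 RNAs before counting, through overlap with another feature or a second copy in the genome of the strain at 0, could not be excluded. The reads they lack amount to at most 0.599% of the reads set aside in any library at 0, so the files leave room for them there. A difference in gene content between the strains, which the design names, also stays open and untested.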

How the results depend on the processing

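Scaling by all assigned reads or by gene reads without TMM, and leaving out copy-suffixed identifiers, RNAs at 0 in a strain, 4.5S alone or tmRNA with srn_4470, were chosen after the data had been seen. The counts of called RNAs stayed within 1.5 times their main values, 99 for all RNAs and 98 for srn_ RNAs, under all 19 alternatives run, from 80 with gene reads as library size to 143 with no low-count filter and, for srn_ RNAs, from 79 to 142. The number of RNAs tested changed as well. The 143 calls came from 467 RNAs tested, a smaller share than 99 of 189, and the fits with 1 library left out tested 172 to 226. Fewer of the original calls recurred than the totals of calls imply: 70 of 99 with total-count scaling, where 5 changed sign, and 74 with no filter, where 2 changed sign. No sign changed under the other alternatives. The replicate number as a block gave 93 called RNAs (92 srn_ RNAs), 91 of them original calls. The numbers did not pair the libraries: same-numbered libraries correlated in their deviations at -0.04, 0.25 and -0.03, and not every library correlated best with its own number. DESeq2 gave 97 and limma-voom 96. Leaving out each library in turn gave 82 to 105 calls (81 to 103 srn_ RNAs). For srn_3910, srn_2230, srn_1590, srn_4710 and 4.5S, direction and call held in all alternatives that tested them, with 4.5S from -4.09 to -2.64. The tmRNA reversed to 0.76 with total-count scaling, which moved the median of all tested RNAs from -0.19 to 0.99 and left tmRNA at -0.25 and -0.23 relative to it. With no filter tmRNA turned to 0.39 without passing the test, 0.63 above a median of -0.24. That median covered 467 RNAs rather than 189, so the 2 medians are not of the same RNAs. RNAseP, from -0.47 to 0.38, and 4.5S, from -3.86 to -3.0, also rose with no filter. The value of 0.63 therefore does not show that tmRNA moved apart from the other RNAs. The tmRNA passed the test with limma-voom at -0.44, and RNAseP passed it without Newman replicate 1, at -0.70; the cause of these was not tested. The lower share of shared RNAs among the assigned reads of Newman, -20.0 percentage points, ran from -22.7 to -18.2 with 1 library left out. Taken of the remaining assigned reads, the difference shrank to -2.76 without 4.5S alone and reversed to 0.699 without 4.5S, tmRNA and srn_4470. Taken of all reads, the share of shared RNAs was instead higher in Newman, at 13.0% against 8.56% in N315. Expressed features numbered 2424 in Newman and 2178 in N315; a minimum of 50 counts left 1301 in N315, where depth is lower, and 1965 in Newman. Thinned libraries gave 1861 in Newman and 2138 in N315. The alternatives for gene lists were not run, because no list had enough members. Depth limits the N315 side, where 3 counts equal up to 3.01 CPM of assigned reads.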

Other observations

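The tests of a mislabelled library and of scaling, and the counts of runs of genes, were chosen after the results had been seen; the others were set before their values were known.

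Part of the genes that set Newman replicate 1 apart lay in runs. Of 2236 genes compared, 99 were over 4-fold lower in replicate 1 than in both other replicates and 33 were over 4-fold higher. Of these, 26 formed 7 runs of at least 3 consecutive locus tags, where shuffled positions put 0.453 genes in such runs on average and 7 genes at most in 1000 shuffles. The longest runs, with 5 genes each, were NWMN_0410 to NWMN_0414 (mean log2 ratio -3.27) and NWMN_1701 to NWMN_1705 (-2.84). The genes are known here by locus tag only. The srn_1930 family, which has 5 numbered copies in Newman and 3 in N315, held 356 to 497 reads per Newman library and 60 to 130 per N315 library. These raw reads do not compare the strains, because the Newman libraries were deeper. The copy srn_1930.3 was among the called RNAs, 4.55-fold higher in N315 (adjusted p = 0.00026 by edgeR). That copy held 59 to 127 reads per N315 library, close to the family's range there. In Newman it held 98 to 126, while srn_1930.5, which is listed for Newman alone, held 161 to 290. The call therefore compares 1 copy and not the family, which was not tested between the strains. The split of reads between copies is uncertain, which also limits that call.

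For the separation of Newman replicate 1, 3 technical explanations were weighed. Lower depth is argued against, because the gap in correlation was 0.0911 and stayed at 0.0954 or more in 20 thinnings to equal totals. Independent noise per gene is argued against, because the log2 ratio of replicate 1 to the others correlated between consecutive locus tags (r = 0.438, rho = 0.44 over 2060 pairs, permutation p = 1e-05, the smallest possible), although genes are not independent replicates and replicates 2 and 3 also showed such a correlation at r = 0.284. An N315 library under a Newman label is argued against, because over the shared RNAs it correlated at 0.562 with N315 and 0.962 with the other Newman libraries. The labels put all libraries in exponential growth; a difference in growth within that phase, or in library batch, stays open, as the labels give neither, and no biological explanation was tested.

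For the higher 4.5S RNA of N315, scaling between libraries is argued against, because the lowest N315 ratio of 4.5S to tmRNA reads was 8.07 times the highest Newman ratio. Differences between the strains in fragment size selection, in the annotated 4.5S interval or in reads set aside as ambiguous were not tested and stay open, as does a difference between the strains themselves.

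The share of other groupings bears on the count of called RNAs. The 10 splits of the 6 libraries cannot give a share under 0.05. The real split, which was 1 of 10 with as many calls, gave 99 called RNAs and 98 srn_ RNAs. The highest of the others gave 0 by edgeR, with at most 7 RNAs at an unadjusted p under 0.05. Every other split mixed both strains in each group, so the strain difference entered the spread within groups. Few calls were thus built into those splits, and the contrast excludes nothing. DESeq2 and limma-voom were not run on the splits.

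A hypothesis was that small RNAs with consecutive srn_ numbers differ between strains together. Their log2 fold changes correlated at r = 0.222 (rho = 0.28) over 76 pairs, with a permutation p = 0.0553, so the hypothesis was not borne out at the threshold. The prediction had counted such a p against the hypothesis, but with r above the 0.1 set in advance a missed threshold excludes nothing, and the question stays open.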
